A study of Homo sapiens with 12 samples.

How the data were processed

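Gene expression was measured with Illumina BeadChip arrays in A375, an established human melanoma cell line. Per the labels, cells were treated with trifluridine (trifluorothymidine, TFT), lactimidomycin (LTM) or the vehicle DMSO for 8 h or 24 h before harvest. Each drug was given at its 75% inhibitory concentration, which the authors had measured after 72 h of treatment. Total RNA was extracted with TRIzol and RNeasy columns. From each sample, 300 ng was amplified and labelled with biotin by the Eberwine method (in vitro transcription from a cDNA copy). All 12 arrays lay on a single BeadChip, and their order on it followed the groups.

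The deposited signal table gives, per the file headers, a mean fluorescence intensity and a detection p-value for 47,230 probes on each of the 12 arrays. The p_value columns are detection p-values of the single probe on the single array. The intensity columns were background-subtracted and not normalized between arrays, since 27.7% to 29.8% of the values on each array lay below 0. GenomeStudio is named per the labels as the authors' software, with no version. A second deposited intensity table by the authors holds 38,221 of these probes on a linear scale, nearly equal in distribution between arrays and never below 11.4. How it was normalized, and why 9009 probes are absent from it, is not stated. The deposited bead summaries give, per the file headers, the mean intensity and the number of beads (bead number, a unit other than expression) for each bead type. They served to check the depth of each array, and the values of single beads and the scanner metrics were not used.

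The signal table was background-corrected, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with the detection p-values as the guide to background and an offset of 16. Probes were kept when the detection p-value was below 0.01 on at least 2 of the 12 arrays, which left 19,588 probes. Symbols came from the annotation of the authors' table and were checked against current names through the Entrez ID, for 26,969 probes, which changed 0 symbols. In all, 27,003 probes had a single symbol, 4 had several and 20,223 had none. For a gene with several kept probes, the probe with the highest mean log2 value stood for the gene. This gave 16,400 features, which were 10,766 named genes and 5634 unnamed probes. Counts below are of named genes, but every p-value was adjusted over all 16,400 features. Gene positions are from RefSeq on GRCh38.p14.

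Samples were grouped by their titles into control (n = 2), TFT 8 h (n = 3), TFT 24 h (n = 2), LTM 8 h (n = 3) and LTM 24 h (n = 2). The controls carry no time, so the same 2 controls served both times and a change against control may include effects of time in culture. LTM 8 h replicate 1 has 8 h in its title and 24 h in its time field; it was kept with the 8 h group. The labels do not say whether samples of a group were separate cultures. If they were not, the p-values measure only the spread between these samples, which would then be technical.

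A group-means model over all 12 arrays was fitted with limma (lmFit, contrasts.fit, eBayes), with 7 residual degrees of freedom and 4.63 from the prior. There were 9 comparisons: each drug and time against control, 24 h against 8 h within each drug, LTM against TFT at each time, and the difference between the drugs in their change from 8 h to 24 h (time by drug interaction). Tests were two-sided moderated tests, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 within the comparison. Errors of log2 changes are standard errors (SE) from this model. Where a gene was below detection on every array of 1 group and detected in the other, the fold is given as a lower bound. It was computed against the lowest detected signal of each array of the undetected group. No fold is given where both groups were below detection.

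Of 25 gene lists written before the data were examined, with 688 genes of which 553 were measured, the 23 with at least 5 measured genes were tested. The lists were p53 targets, DNA replication and G1/S genes, mitotic genes, replication-dependent histone genes, thymidylate, folate and pyrimidine genes, ATF4 and integrated stress response genes, ER chaperone genes, immediate-early genes, NF-kB and chemokine genes, interferon-stimulated genes, cytosolic ribosomal protein genes, nucleolar ribosome biogenesis genes, long noncoding RNAs degraded during translation, translation factors, cholesterol synthesis genes, melanocyte lineage genes, ERK output genes, undifferentiated melanoma genes, heat shock genes, BCL2 family and cell death genes, oxidative phosphorylation genes, hypoxia and glycolysis genes, and markers of fibroblasts, keratinocytes and blood cells. The noncoding RNA list, in full host-gene and other long noncoding RNAs degraded during translation, includes TUG1, NEAT1 and MALAT1. Its name was set with the list, and degradation of its members was not tested. The list test was camera of limma with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 207 tests. Camera with an estimated correlation and fry were run beside it. Some lists share measured genes, so their tests are not independent. SESN2 is in the p53 and ATF4 lists, and BAX, FAS, PMAIP1 and TNFRSF10B are in the p53 and BCL2 family lists. Immediate-early genes share EGR1, FOSL1 and IER3 with ERK output genes, and CCN1, CCN2 and FOSL1 with undifferentiated melanoma genes. They also share MCL1 with BCL2 family genes. ERK output genes share CXCL8 and LIF with NF-kB genes. Where a count is called "adjusted over the list alone", p-values of the list's genes were adjusted within the list.

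Genes named in the text follow a rule written before the data were examined. For each drug against control these are the 10 largest increases and the 10 largest decreases, and for the other comparisons the 5 and 5. They were taken among called genes whose 2 groups did not overlap and that were detected on every array of at least 1 group; for the interaction the condition on overlap was left out. Unnamed probes and provisional symbols (LOC, HS., FLJ, MGC, KIAA) were tested but not named. From each list the up to 4 called members with the largest change were taken, or the 2 brightest if none was called. TYMS, TK1, CDKN1A, MDM2, ATF3, DDIT3, HSPA5 and MYC were always taken against control.

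Alternatives written before the data were examined were: no background correction; median scaling in place of quantile normalization; no detection filter or detection on all 12 arrays; the mean of a gene's probes; the authors' value table; only the arrays of the groups compared; a variance trend with robust prior; array weights; the replicate number as a block; a linear term for array position; LTM 8 h replicate 1 grouped with 24 h; a 2-fold threshold; and leaving out each array in turn. Added after seeing the data were fits without the 2 dimmest arrays (TFT 8 h replicate 1 and LTM 24 h replicate 1), array brightness as a covariate, crossed pairing, and list tests with each array left out. The pipeline from the fit onward was tested on simulated log2 values with 200 changed genes. It recovered 0% to 7.58% of changes of 0.5 log2, 35.8% to 83.6% of changes of 1 log2 and 95.5% to 100% of changes of 2 log2, none with the wrong sign, with 2 to 9 false calls. A list shifted by 0.5 log2 was called and 0 of the 22 other lists were. Noise was drawn independently for each gene and array, so these runs cannot show false calls from correlation between genes. Normalization and filtering were not simulated. Figures were drawn with matplotlib 3.10.9.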

Results

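Transcript levels were measured in A375, an established human melanoma cell line, after treatment with trifluridine (TFT), lactimidomycin (LTM) or the vehicle DMSO. TFT is a thymidine analogue that is built into DNA and inhibits thymidylate synthase, and LTM is a glutarimide natural product that blocks translation elongation. Per the labels, the drug responses of cell lines were collected as signatures to be set against the outcome of melanoma patients. There were 12 arrays: 2 controls, 3 of TFT at 8 h, 2 of TFT at 24 h, 3 of LTM at 8 h and 2 of LTM at 24 h. Each array read 989,776 to 1,070,130 beads, with a median of 20 to 22 beads per bead type, and 15,740 to 17,480 of the 47,230 probes (33.3% to 37.0%) were detected. The number of arrays limits the precision, and the controls give the background for every change against control.

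The 75th percentile of the signal was 67.3 on LTM 24 h replicate 1 and 75.1 on TFT 8 h replicate 1, the dimmest arrays, and 85.8 to 114 on the other 10. Correlations within groups were 0.990 between the controls, 0.996 between TFT 8 h replicates 2 and 3, 0.995 within TFT 24 h and 0.989 to 0.993 within LTM 8 h. They were 0.971 and 0.972 between TFT 8 h replicate 1 and its group and 0.969 within LTM 24 h. The first principal component took 57.6% of the variance and separated LTM from the other arrays, with LTM 24 h farthest out. The second took 15.9% and had both dimmest arrays at its upper end.

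**Figure D1:**
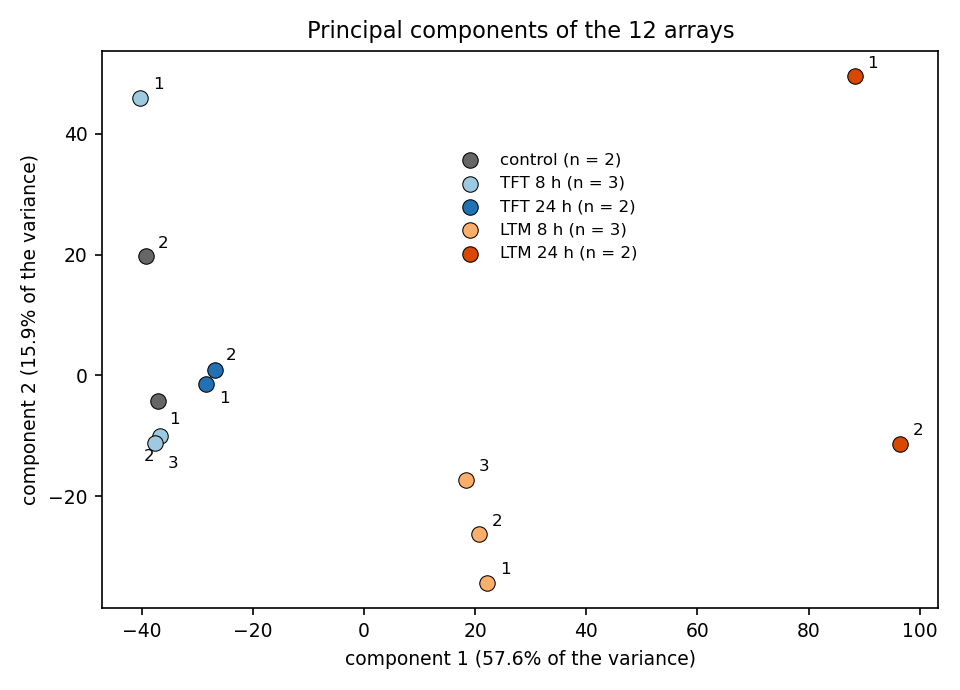
Scores of the 12 arrays on principal components 1 (x axis, 57.6% of the variance) and 2 (y axis, 15.9%), arbitrary units, each point an array coloured by group. The 5 LTM arrays lie to the right of the other 7, and LTM 24 h replicate 1 and TFT 8 h replicate 1 lie highest.

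Named genes changed in every comparison, from 33 after 8 h of TFT to 5386 after 24 h of LTM. Of the 23 tested lists in 9 comparisons, 85 of 207 tests passed, 2 of them also with an estimated correlation between genes; both were p53 targets, TFT 24 h against control and against TFT 8 h. In the 85 tests that passed, the median, mean and test of the list had the same sign, while in 21 of the other 122 the signs differed. Array position on the chip followed the groups, so position and treatment are confounded. With a linear term for position, the counts against control were 0, 8, 0 and 0 for TFT 8 h, TFT 24 h, LTM 8 h and LTM 24 h, beside 629, 686 and 1375 genes at an unadjusted p under 0.05 in limma for the 3 counts of 0, TFT 8 h, LTM 8 h and LTM 24 h.

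**Figure D2:**
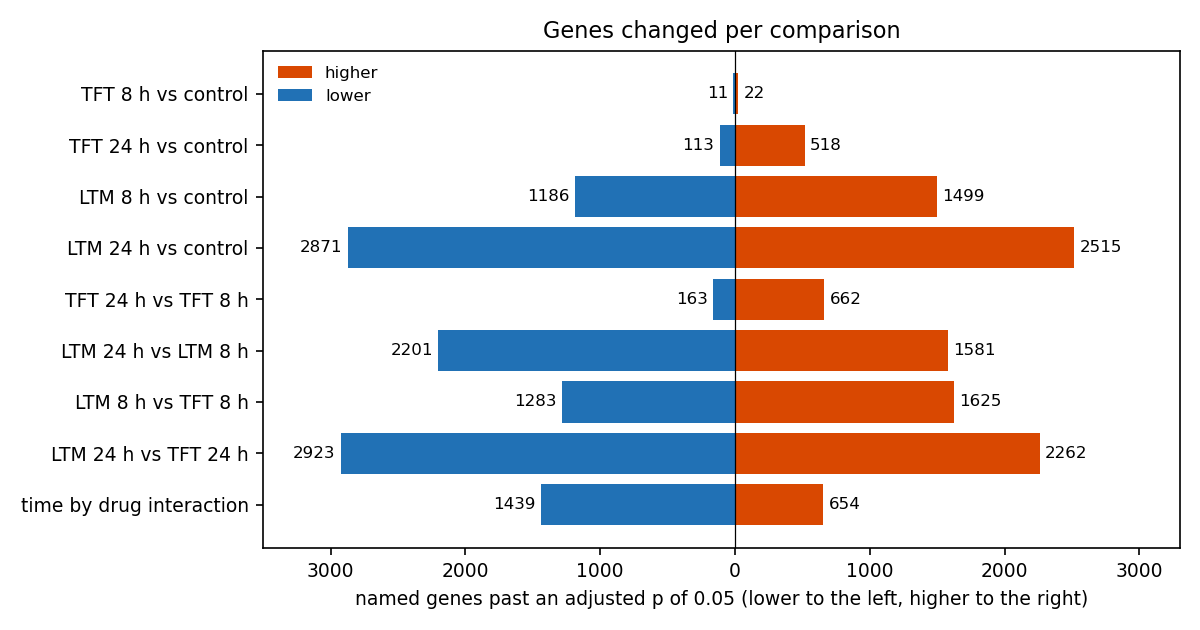
Number of named genes past an adjusted p of 0.05 in each of the 9 comparisons (x axis, number of genes; higher to the right, lower to the left of 0). The bars run from 22 higher and 11 lower for TFT 8 h against control to 2515 higher and 2871 lower for LTM 24 h against control.

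The first comparison addressed the early response to TFT, 8 h against control. Mitotic genes fell in 6 of 38, the list with adjusted p = 0.0571 with an estimated correlation. KIF20A, a kinesin of late mitosis (Entrez ID 10112, GRCh38.p14 chromosome 5, 138179112 to 138187723), fell by 1.62 on the log2 scale (SE 0.18, n = 3 TFT and 2 control arrays, adjusted p = 0.0062). CENPA, the histone variant of centromeres, fell by 1.19 (SE 0.19; -1.01 at its other probe, not called), and PLK1 and CDC25C, which drive entry into mitosis, had changes of -1.42 (SE 0.24) and -1.10 (SE 0.18; -1.14 and -0.64 at its other probes, not called). The largest fitted increase was in ANKRD1, a nuclear ankyrin repeat protein (Entrez ID 27063, chromosome 10, 90912096 to 90921087), at 1.79 (SE 0.22, adjusted p = 0.0092). KCNH1, a potassium channel, rose by 1.65 (SE 0.15), at least 2.90-fold from below detection, PLXNA2, a semaphorin receptor, by 1.64 (SE 0.16; 0.47 at its other probe, not called), and CPA4, a carboxypeptidase, by 1.53 (SE 0.18). The rest of the 10 largest increases, TNS1, PITX1, EPHB1, PRR5, ANGPTL4 and ALPK2, lay between 1.17 and 1.49, and the rest of the decreases, MXD3, PIF1, AURKA, CCNB2, SHISA2 and MAP2K6, between -1.32 and -1.01. ANGPTL4 rose on 1 probe, against 0.19 and 0.11 at its other probes. TYMS, the enzyme that TFT inhibits, had a change of -0.26 (SE 0.19, adjusted p = 0.864), and TK1, the kinase that activates TFT, of -0.03 (SE 0.20, adjusted p = 0.999). The p53 target MDM2 had a change of 0.13, the stress genes ATF3 -0.06, DDIT3 -0.41 and HSPA5 0.48, and MYC 0.35, none past the threshold. CDKN1A was below detection in both groups. In all, 33 genes changed, 22 up and 11 down, and 16 of the 22 and 10 of the 11 did so at least 2-fold. Under median scaling 13 genes changed, 53.8% of them up against 66.7%. Without control replicate 1 no gene passed in limma (569 at an unadjusted p under 0.05), KIF20A then at -1.43 (adjusted p = 0.126). The count was 4 without control replicate 2, 5 and 10 without TFT 8 h replicates 2 and 3, 10 without either TFT 24 h replicate, and 14, 18 and 19 without LTM 8 h replicates 1, 2 and 3. It was 0 with only the groups compared (676 at an unadjusted p under 0.05), 0 with LTM 8 h replicate 1 grouped with 24 h (373), and 2 with the replicate block. In contrast it was 50 without a detection filter, 208 without the 2 dimmest arrays, 241 with brightness as a covariate and 443 with array weights. Over the 12 fits that each left out an array, PLK1 lay between -1.66 and -1.19 with its call lost in 10, CENPA between -1.37 and -1.01 (lost in 8), CDC25C between -1.17 and -1.02 (lost in 9) and ANKRD1 between 1.72 and 1.91 (lost in 3).

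Of 38 mitotic genes, 6 fell and 28 did when adjusted over the list alone, with none up (median -0.69, camera adjusted p = 7.8e-36, adjusted p = 0.0571 with an estimated correlation). On dim TFT 8 h replicate 1 the list lay 0.42 below the mean of the other TFT 8 h arrays, and without the 2 dimmest arrays 16 of the genes fell. For 5 more lists the test passed although no member did over all genes. Nucleolar ribosome biogenesis genes had a median of 0.15 over 32 genes (adjusted p = 0.0024), undifferentiated melanoma genes 0.14 over 16 (0.0049; 2 up adjusted over the list alone) and BCL2 family and cell death genes 0.15 over 20 (0.0412). Histone genes had a median of -0.32 over 17 (0.006; 1 down adjusted over the list alone) and translation factors -0.12 over 35 (0.036). These 5 had adjusted p = 0.0715, 0.404, 0.194, 0.474 and 0.438 with an estimated correlation, in that order. Leaving out control replicate 2 ended the calls of histone (adjusted p = 0.142), undifferentiated melanoma (0.109), BCL2 family (0.129) and translation factor genes (0.0623). The translation factor call also ended without control replicate 1 (0.0964) and TFT 8 h replicate 1 (0.182), that of BCL2 family genes without TFT 8 h replicates 1 (0.0743) and 2 (0.08), and that of histone genes without TFT 8 h replicates 2 (0.0889) and 3 (0.0737). The translation factor and BCL2 family calls ended without the 2 dimmest arrays (0.239 and 0.0812) and with brightness as a covariate (0.102 and 0.0804), and with linear position the histone median turned to 0.047. In the other 17 lists no gene passed, and neither did the list.

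The comparison of TFT at 24 h with control addressed the later response to the same drug. Of 28 p53 targets 18 rose. GDF15, a stress-induced cytokine (Entrez ID 9518, GRCh38.p14 chromosome 19, 18386158 to 18389176), rose by 6.59 log2 from below detection (SE 0.18, n = 2 and 2 arrays, adjusted p = 4.2e-09), at least 67.3-fold. ATF3, a stress-induced transcription factor, rose by 3.78 (SE 0.23), PTGS2, the inducible prostaglandin synthase, by 3.52 (SE 0.37), and IL24, a cytokine, by 2.92 (SE 0.18). Increases from below detection were at least 5.20-fold for HES2 (1.31 log2 at its other probe), 4.99-fold for the adhesion protein CEACAM1 (2.07 and 1.03), 4.90-fold for the adhesion protein NECTIN4 and 4.72-fold for ARC. TRIML2 rose by 2.92, and 1 probe of ANGPTL4 rose by 3.22 (SE 0.21) while its other 2 gave -0.19 and 0.37. Among the decreases, E2F2, a transcription factor of the cell cycle, fell by 1.59 (SE 0.19) and the small nucleolar RNA gene SNORD110 by 1.20 (SE 0.16). MIX23, a mitochondrial protein (Entrez ID 131076, chromosome 3, 122359591 to 122383231), had a change of -2.81 (SE 0.47, at least 5.74-fold to below detection). It was not called without control replicate 2 (-2.59, adjusted p = 0.0582) or TFT 24 h replicate 2 (-2.59, adjusted p = 0.0738). ECT2, SAP30, HMGB1, SNORD96A, HMGB2, TRMT10C and FOXD2-AS1 lay between -1.54 and -1.20, each losing its call in at least 1 fit that left out an array. TYMS (-0.17), TK1 (-0.09), HSPA5 (-0.21) and MYC (0.44) did not pass. Of 631 genes changed, 518 rose and 113 fell, 306 and 35 of them at least 2-fold. The count was 216 and 214 without control replicates 1 and 2, and 234 and 172 without TFT 24 h replicates 1 and 2. Without the 2 dimmest arrays it was 1628, with brightness as a covariate 1430, with array weights 1706 and with only the groups compared 1309. With the replicate block it was 396, with detection on all arrays 384, and with LTM 8 h replicate 1 grouped with 24 h 170.

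No p53 target fell, and 22 rose adjusted over the list alone (median 1.53, camera adjusted p = 6.1e-25, adjusted p = 0.0016 with an estimated correlation). MDM2, the ubiquitin ligase that restrains p53, rose by 2.41 (SE 0.19), SESN2, a stress-induced regulator of mTORC1, by 2.63 (SE 0.18) and TP53INP1 by 2.61 (SE 0.28). CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 2.11 from below detection (SE 0.21, adjusted p = 1.9e-04), at least 3.53-fold. Of 33 ATF4 and integrated stress response genes, 13 rose and none fell, 17 up and 1 down adjusted over the list alone (median 0.63, adjusted p = 4.3e-11, adjusted p = 0.0648 with an estimated correlation), among them DDIT3 (2.25, SE 0.30) and STC2 (1.75, SE 0.21). Of 29 immediate-early genes, 11 rose, 16 adjusted over the list alone (median 0.67, adjusted p = 2.7e-09, adjusted p = 0.131 with an estimated correlation), with EGR1 at 2.27 (SE 0.28), FOS at 1.93 (SE 0.20) and JUN at 1.91 (SE 0.28). Of 19 NF-kB and chemokine genes, 5 rose, 7 adjusted over the list alone (median 0.47, adjusted p = 1.7e-04, adjusted p = 0.131 with an estimated correlation), among them the cytokine IL1B (2.1, SE 0.22) and TNFAIP3 (1.73, SE 0.26). Interferon-stimulated genes had 2 of 24 up, 6 adjusted over the list alone (median 0.41, or 0.35 with undetected genes at their bounds, adjusted p = 0.0018, adjusted p = 0.130 with an estimated correlation).

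Of the mitotic genes, 4 of 38 fell in TFT at 24 h, 7 adjusted over the list alone (median -0.45, adjusted p = 3.5e-09, adjusted p = 0.183 with an estimated correlation). Over fits that each left out an array these 4 lay between -1.21 and -0.85 for CDCA3 (call lost in 9 of 12), -1.13 and -0.76 for CCNB1 (7), -0.95 and -0.73 for CCNA2 (6) and -0.84 and -0.60 for CDC20 (7). DNA replication and G1/S genes had 3 of 36 down, 7 adjusted over the list alone (median -0.13, adjusted p = 0.0018, adjusted p = 0.404 with an estimated correlation). ERK output genes had 4 of 20 up, 5 adjusted over the list alone (median 0.23, adjusted p = 0.0495, adjusted p = 0.26 with an estimated correlation). Of these 4, EGR1 and IER3 were also in the immediate-early list and LIF in the NF-kB list. The ERK call ended under median scaling (adjusted p = 0.121) and without control replicate 2 (0.0935), TFT 24 h replicate 1 (0.0674) or LTM 8 h replicates 2 (0.0557) and 3 (0.0579), and with brightness as a covariate (0.14). The other 15 lists did not pass. Among them 3 of 20 BCL2 family and cell death genes rose and 1 fell, with BCL2 at -1.07 (SE 0.16; -0.72 at its other probe, not called) and the death receptor TNFRSF10A at 1.26 (SE 0.18). Of 23 thymidylate, folate and pyrimidine genes 1 fell, and none of 17 histone, 49 ribosomal protein, 13 melanocyte lineage or 6 fibroblast marker genes passed over all genes tested. Of 4 measured blood cell markers LYZ rose, from below detection, by at least 2.17-fold. Both of 2 measured keratinocyte markers rose, SFN at least 1.34-fold from below detection and KRT15 by 0.96 (SE 0.25), though KRT15 lost its call in 9 of 12 fits that left out an array (0.80 to 1.12).

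The comparison of LTM at 8 h with control addressed the early response to a block of translation. Immediate-early genes rose in 22 of 29 and NF-kB genes in 14 of 19, with adjusted p = 0.0715 and 0.0629 with an estimated correlation. TNFAIP3, a ubiquitin-editing inhibitor of NF-kB (Entrez ID 7128, GRCh38.p14 chromosome 6, 137866349 to 137883312), rose by 3.75 log2 (SE 0.23, n = 3 LTM and 2 control arrays, adjusted p = 5.5e-06). FOS, a subunit of AP-1 (Entrez ID 2353, chromosome 14, 75278828 to 75282230), rose by 3.19 (SE 0.18), FOSB by 3.11 (SE 0.22), RGS2, a regulator of G protein signalling, by 3.20 (SE 0.17), the kinase NUAK2 by 3.48 (SE 0.18) and the protease ADAMTS6 by 3.65 (SE 0.27). The ligand NRG1 rose by 3.09 (SE 0.28, 1.84 and 0.85 at its other probes), IL24 by 3.09, the zinc exporter SLC30A1 by 3.02 and GDA by 3.01. The receptor kinase ERBB3 fell by 2.44 (SE 0.22, -0.98 and -1.04 at its other probes), the potassium channel subunit KCNS3 by 2.80 (SE 0.19), the ligand WNT5A by 2.52 (SE 0.32) and the hyaluronan synthase HAS2 by 2.40 (SE 0.32, -1.52 at its other probe). CHST1 fell at least 4.32-fold to below detection, and VSNL1, CERK, TMEM19, LRFN3 and TGFBR3 had changes of -2.25 to -2.08. MYC rose by 1.92 (SE 0.17) and MDM2 by 0.97 (SE 0.18), TK1 had a change of -0.56 (adjusted p = 0.0614), and CDKN1A was below detection in both groups. TYMS, at -0.71 (SE 0.19, adjusted p = 0.0189), lost its call without control replicate 1 (-0.67), control replicate 2 (-0.75) or LTM 8 h replicate 2 (-0.60). HSPA5, at -0.57 (adjusted p = 0.0126), lost it under median scaling (-0.53) and without control replicates 1 (-0.56) and 2 (-0.58). Of 2685 genes changed, 1499 rose and 1186 fell, 667 and 304 of them at least 2-fold. The count was 1370 and 1219 without control replicates 1 and 2 and 1779 without LTM 8 h replicate 1, and 4588 without the 2 dimmest arrays. It was 4290 with brightness as a covariate, 4490 with array weights and 734 with LTM 8 h replicate 1 grouped with 24 h.

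Of the immediate-early genes, 22 of 29 rose after 8 h of LTM, 23 adjusted over the list alone (median 1.25, camera adjusted p = 8.1e-14, adjusted p = 0.0715 with an estimated correlation), with EGR1 at 2.95 (SE 0.26). Of the NF-kB and chemokine genes, 14 of 19 rose and 1 fell, 16 and 1 adjusted over the list alone (median 1.22, adjusted p = 3.5e-09, adjusted p = 0.0629 with an estimated correlation), with RELB at 2.29 (SE 0.19) and NFKB2 at 2.06 (SE 0.17, with 1.60 and 0.26 at its other probes, the latter not called). Of the mitotic genes, 19 of 38 fell, 20 adjusted over the list alone (median -0.68, adjusted p = 3.2e-08, adjusted p = 0.203 with an estimated correlation), among them CCNB1 (-1.65, SE 0.21) and KIF20A (-1.41, SE 0.18). Nucleolar ribosome biogenesis genes rose in 12 of 32, 17 adjusted over the list alone (median 0.54, adjusted p = 2.4e-05, adjusted p = 0.0571 with an estimated correlation), for example POLR1C, a subunit of RNA polymerases I and III (0.98, SE 0.17). Replication-dependent histone genes rose in 6 of 17, 7 adjusted over the list alone (median 0.81, or 0.70 with bounds, adjusted p = 1.2e-04, adjusted p = 0.360 with an estimated correlation), with H2AC6 at 2.62 (SE 0.21) and H4C14 at 2.25 (SE 0.28). ERK output genes had 9 of 20 up and 1 down, 11 and 1 adjusted over the list alone (median 0.49, adjusted p = 9.3e-04, adjusted p = 0.130 with an estimated correlation).

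Another 5 lists passed in LTM at 8 h. Of 11 genes in the list of noncoding RNAs degraded during translation, 6 rose and 1 fell, the same numbers adjusted over the list alone (median 0.85, adjusted p = 0.0222), with SNHG15 at 1.78 (SE 0.28). Of 33 ATF4 and integrated stress response genes 11 rose and 3 fell, 13 and 3 adjusted over the list alone (median 0.29, adjusted p = 0.0355), with PPP1R15A, a phosphatase subunit acting on eIF2, at 2.64 (SE 0.22). Of 17 heat shock genes 1 rose and 3 fell, likewise over the list alone (median -0.36, adjusted p = 0.0152), with HSPA1B at -1.41 (SE 0.15). Of 32 oxidative phosphorylation genes 3 fell, likewise over the list alone (median -0.28, adjusted p = 0.0116), and of 36 DNA replication and G1/S genes 7 fell, 6 adjusted over the list alone (median -0.15, adjusted p = 0.0495). These 5 lists had adjusted p = 0.577, 0.404, 0.26, 0.585 and 0.575 with an estimated correlation, in that order. With linear position the oxidative phosphorylation median turned to 0.578. Without control replicate 1 the calls of the noncoding RNAs, heat shock and G1/S genes ended, and without control replicate 2 those of ATF4 and oxidative phosphorylation genes. Such fits have fewer arrays, so a lost call may also come from lower precision. The ATF4 call also ended without LTM 8 h replicate 3 (adjusted p = 0.0531), and the G1/S call without LTM 8 h replicate 2 (0.0708), TFT 8 h replicate 2, TFT 24 h replicate 1 or TFT 24 h replicate 2 (0.0513 each). Both ended with brightness as a covariate (0.0604 and 0.0575). Of the 12 lists that did not pass, p53 targets had 8 of 28 up and 2 down, with GADD45A at 2.60 (SE 0.18). ER chaperone genes had 1 up and 1 down of 22, translation factors 3 up and 2 down of 35, ribosomal protein genes 1 down of 49 (none adjusted over the list alone) and fibroblast markers 1 down of 6.

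**Figure D3:**
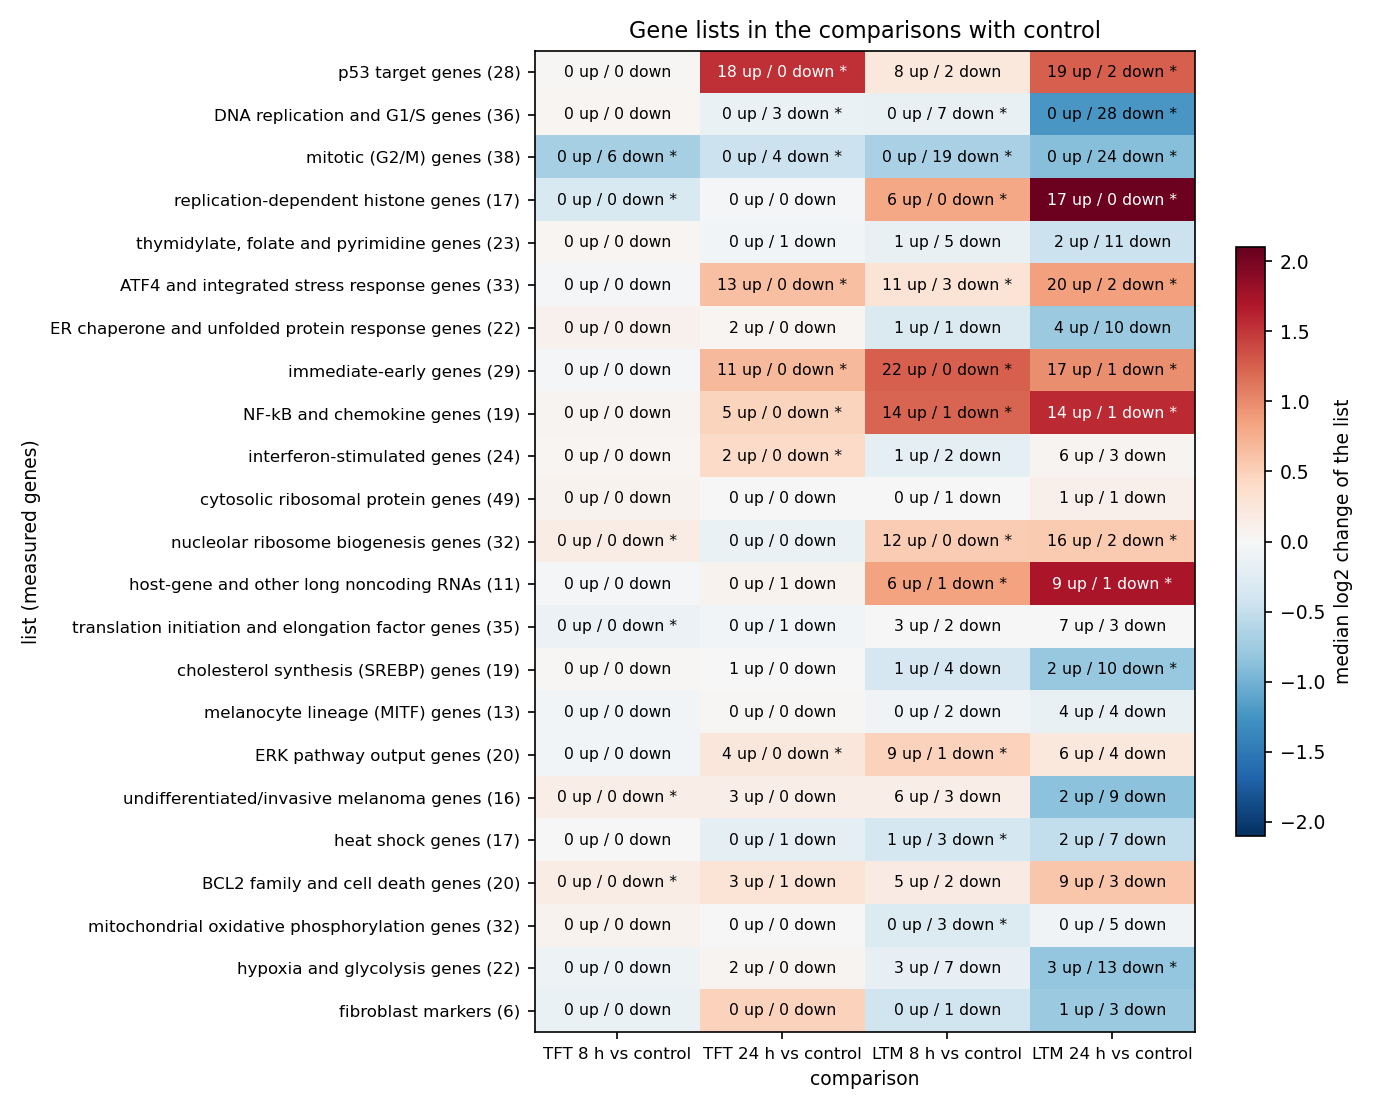
Median log2 change (colour) of each of the 23 tested gene lists (rows, with the number of measured genes) in the 4 comparisons of drug with control (columns). Each cell gives the genes up and down at an adjusted p of 0.05, and an asterisk marks lists that passed the list test; histone genes reached a median of 2.06 with 17 of 17 up in LTM 24 h.

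The comparison of LTM at 24 h with control addressed the later response to a translation block. Replication-dependent histone genes were among the largest increases, while 28 of 36 DNA replication and G1/S genes fell, as did TYMS. The 2 lists had adjusted p = 0.207 and 0.194 with an estimated correlation. H4C8, a histone H4 gene (Entrez ID 8365, GRCh38.p14 chromosome 6, 26285126 to 26285534), rose by 6.33 log2 from below detection (SE 0.29, n = 2 and 2 arrays, adjusted p = 1.1e-07), at least 52.0-fold. H2AC6 rose by 4.76 (SE 0.23), H4C14 by 4.68 (SE 0.31), H2BC5 by 4.51 (SE 0.38) and PGM5P2 by 4.34 (SE 0.20, 2.91 at its other probe). From below detection, the natriuretic peptide gene NPPB rose at least 28.9-fold, C6orf58 25.4-fold, the phospholipase PLA2G4C 19.7-fold, the cytokine IL32 17.2-fold and RERGL 11.8-fold. CEMIP, a hyaluronan-degrading protein (Entrez ID 57214, chromosome 15, 80779370 to 80951771), fell by 4.28 to below detection (SE 0.17, adjusted p = 1.0e-07), at least 10.6-fold, and COLEC12 at least 10.1-fold. NREP fell by 4.14 (SE 0.25), HOXB8, a developmental transcription factor, by 4.11 (SE 0.24), KCNS3 by 4.04 (SE 0.21) and ERBB3 by 4.05 (SE 0.24, -1.86 and -1.66 at its other probes). TNS3, SIRPA, DPYSL2 and SFRP1 had changes of -3.92, -3.72 (-1.48 at the other probe), -3.70 and -3.70. TYMS fell by 2.58 (SE 0.21, adjusted p = 2.3e-06), TK1 by 1.30 (SE 0.22) and HSPA5 by 1.08 (SE 0.15), while MDM2 rose by 1.90 (SE 0.19) and MYC by 1.16 (SE 0.18; 0.82 at its other probe, not called). CDKN1A, at 0.63 (SE 0.21, at least 1.26-fold), lost its call under median scaling (0.44) and without control replicate 2 or LTM 24 h replicate 1 (0.41 each). Of 5386 genes changed, 2515 rose and 2871 fell, 1595 and 1727 of them at least 2-fold. Under median scaling 34.6% of 4991 changed genes rose, against 46.7%, and the median of all genes was -0.213 log2; without the 2 dimmest arrays 6417 genes changed, and with LTM 8 h replicate 1 grouped with 24 h 3520.

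**Figure D4:**
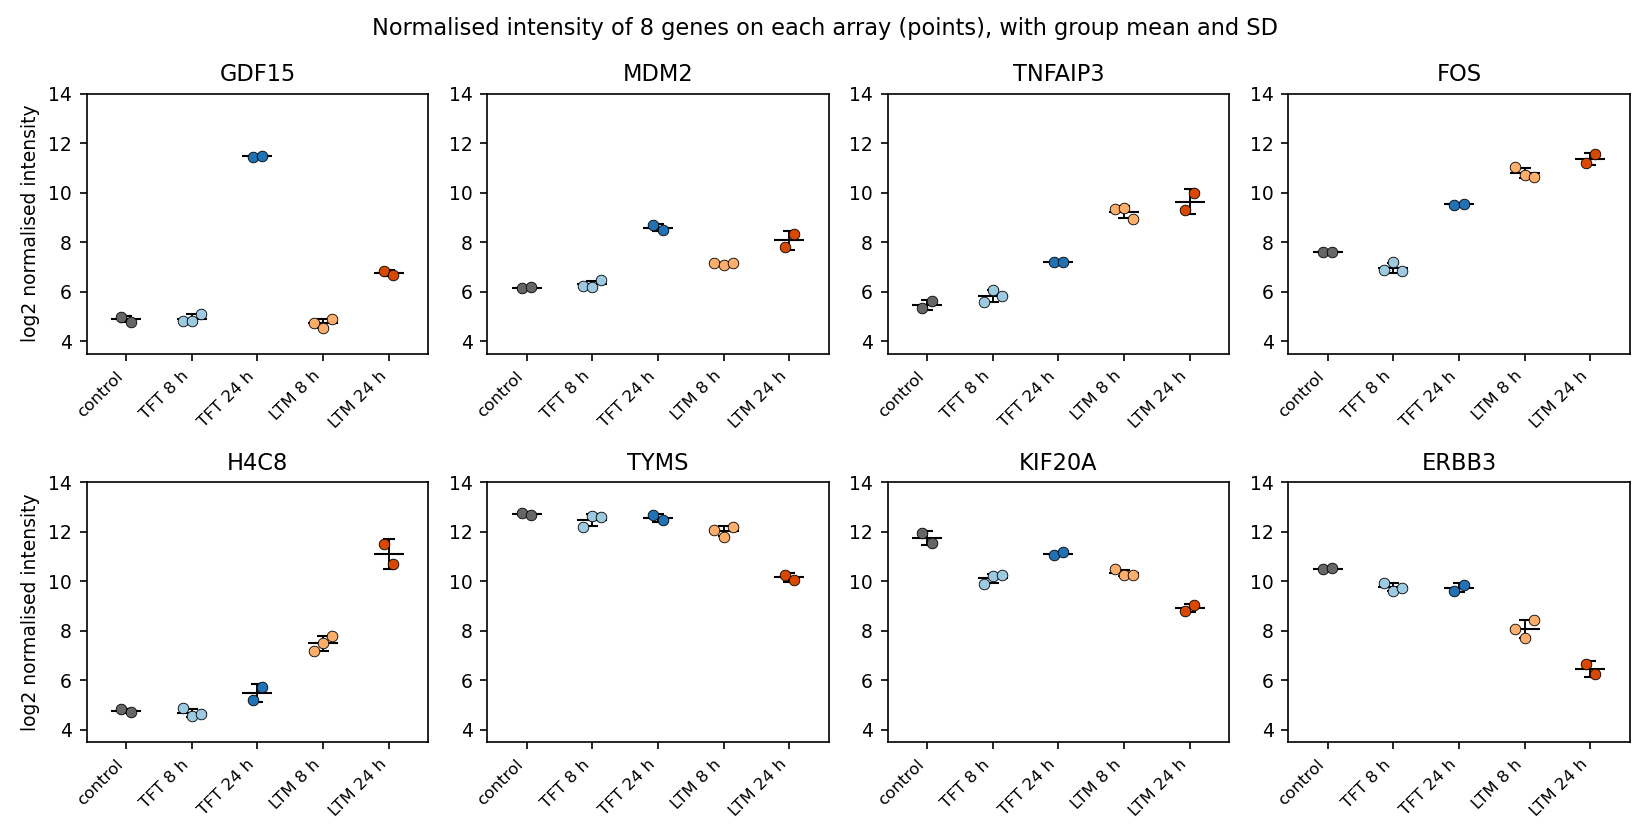
Log2 normalised intensity (y axis) of GDF15, MDM2, TNFAIP3, FOS, H4C8, TYMS, KIF20A and ERBB3 on each array (points) by group (x axis), with the group mean and SD (bars). From control below detection, GDF15 was at least 67.3-fold higher in TFT 24 h and H4C8 at least 52.0-fold higher in LTM 24 h, and TYMS was 2.58 lower there.

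All 17 measured histone genes rose after 24 h of LTM, also adjusted over the list alone (median 2.06, camera adjusted p = 1.1e-08, adjusted p = 0.207 with an estimated correlation). The list lay 0.83 higher on dim LTM 24 h replicate 1 than on replicate 2, and without the 2 dimmest arrays its median change was 1.71. Of DNA replication and G1/S genes, 28 of 36 fell, 29 adjusted over the list alone (median -1.23, adjusted p = 4.9e-09, adjusted p = 0.194 with an estimated correlation), with the ribonucleotide reductase subunit RRM2 at -2.90 (SE 0.42) and the cyclin CCNE1 at -2.61 (SE 0.17). Of mitotic genes, 24 of 38 fell, 28 adjusted over the list alone (median -0.89, adjusted p = 3.8e-06, adjusted p = 0.256 with an estimated correlation), with KIF20A at -2.82 (SE 0.20). The mitotic list lay 0.36 lower on LTM 24 h replicate 1 than on replicate 2. Of 23 thymidylate, folate and pyrimidine genes, 11 fell and 2 rose without the list passing (adjusted p = 0.0597), among them DUT, the dUTPase (-2.60, SE 0.21; -0.52 at its other probe, not called), and SHMT1 (-2.30, SE 0.16; -0.56 and -1.91 at its other probes). p53 targets had 19 of 28 up and 2 down, the same adjusted over the list alone (median 1.26, adjusted p = 1.2e-04, adjusted p = 0.0648 with an estimated correlation), with GADD45A at 2.96 (SE 0.20) and SESN2 at 2.73 (SE 0.18) but CMBL at -2.34 (SE 0.17). ATF4 and integrated stress response genes had 20 of 33 up and 2 down, 23 and 4 adjusted over the list alone (median 0.87, adjusted p = 1.2e-05, adjusted p = 0.160 with an estimated correlation), with DDIT3 at 3.86 (SE 0.30), ATF3 at 3.48 (SE 0.23) and the cystathionine lyase CTH at 3.48 (SE 0.20).

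After 24 h of LTM, immediate-early genes had 17 of 29 up and 1 down, 18 and 1 adjusted over the list alone (median 0.97, adjusted p = 1.4e-05, adjusted p = 0.215 with an estimated correlation). NF-kB and chemokine genes had 14 of 19 up and 1 down, 14 and 2 adjusted over the list alone (median 1.56, adjusted p = 5.1e-05, adjusted p = 0.130 with an estimated correlation), with TNFAIP3 at 4.16 (SE 0.26) and RELB at 3.53 (SE 0.21). Nucleolar ribosome biogenesis genes had 16 of 32 up and 2 down, the same over the list alone (median 0.56, adjusted p = 0.0026, adjusted p = 0.0715 with an estimated correlation). The noncoding RNAs degraded during translation had 9 of 11 up and 1 down, the same over the list alone (median 1.72, or 1.68 with bounds, adjusted p = 0.0014, adjusted p = 0.440 with an estimated correlation), with SNHG15 at 3.34 (SE 0.31) and ZFAS1 at 2.79 (SE 0.30). That list lay 0.61 higher on dim LTM 24 h replicate 1 than on replicate 2, and 0.32 higher on control replicate 2 than on control replicate 1. Cholesterol synthesis genes had 10 of 19 down and 2 up, the same over the list alone (median -0.80, adjusted p = 0.0133, adjusted p = 0.162 with an estimated correlation), with the desaturase SCD at -2.60 (SE 0.21) and DHCR7 at -1.96 (SE 0.16). Hypoxia and glycolysis genes had 13 of 22 down and 3 up, 15 and 3 adjusted over the list alone (median -0.81, adjusted p = 0.0253, adjusted p = 0.4 with an estimated correlation), with P4HA2, a collagen prolyl hydroxylase, at -2.83 (SE 0.17); the list did not pass without the 2 dimmest arrays (adjusted p = 0.0552) or with brightness as a covariate (0.0665). Of the 12 lists that did not pass, melanocyte lineage genes had 4 of 13 up and 4 down, with the lineage factor MITF at 1.5 (SE 0.23), and undifferentiated melanoma genes had 2 of 16 up and 9 down. ER chaperone genes had 4 of 22 up and 10 down, interferon-stimulated genes 6 of 24 up and 3 down, heat shock genes 2 of 17 up and 7 down, and ribosomal protein genes 1 of 49 up and 1 down (none adjusted over the list alone). Of the markers of other cell types, fibroblast genes had 1 of 6 up and 3 down, the keratinocyte marker KRT15 rose by 2.42 (SE 0.25) and the blood cell marker CD68 fell by 0.85 (-0.37 at its other probe, not called).

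Both times of TFT were compared directly to ask what came between 8 h and 24 h. GDF15 rose by 6.55 (SE 0.17, n = 2 and 3 arrays, adjusted p = 1.6e-09, at least 64.3-fold) and ATF3 by 3.84 (SE 0.21). PTGS2 rose by 3.33 (SE 0.34), HES2 at least 4.97-fold (1.17 log2 at its other probe) and NECTIN4 at least 4.69-fold. MIX23 fell by 3.14 (SE 0.43, at least 7.22-fold), KCNH1, which had risen at 8 h, fell at least 3.08-fold, E2F2 fell by 1.78 (SE 0.18), and BEND3 by 1.60 (SE 0.18, -0.98 at its other probe). MT1X, at -1.87, lost its call without TFT 24 h replicate 1 (-1.85) or 2 (-1.88). p53 targets had 22 of 28 up and none down, 26 adjusted over the list alone (median 1.43, or 1.38 with bounds, camera adjusted p = 1.6e-25, adjusted p = 0.0016 with an estimated correlation), with CDKN1A at 2.49 (at least 3.37-fold). ATF4 genes had 14 of 33 up, 19 adjusted over the list alone (median 0.69), and immediate-early genes 14 of 29, 15 up and 1 down adjusted over the list alone (median 0.64). NF-kB genes had 5 of 19 up, 7 adjusted over the list alone (median 0.42), and interferon-stimulated genes 6 of 24, 8 adjusted over the list alone (median 0.35). Their adjusted p were 4.5e-12, 7.9e-08, 5.7e-04 and 0.0031. In the same order they had adjusted p = 0.0629, 0.162, 0.160 and 0.132 with an estimated correlation. Mitotic genes had 4 of 38 up, 7 adjusted over the list alone (median 0.35), and ERK output genes 4 of 20 up and 1 down, 5 and 1 adjusted over the list alone (median 0.29). G1/S genes had 6 of 36 down, 10 adjusted over the list alone (median -0.24), and nucleolar genes none of 32 (median -0.31). Their adjusted p were 0.0026, 0.0249, 1.9e-05 and 7.0e-04, and in the same order adjusted p = 0.404, 0.225, 0.26 and 0.0629 with an estimated correlation. The ERK call ended under median scaling (adjusted p = 0.0651), without TFT 8 h replicate 1 (0.0601) and without the 2 dimmest arrays (0.0508), and with brightness as a covariate the ERK (0.14) and mitotic calls (0.0706) ended. In all 825 genes changed, 662 up and 163 down, 304 and 34 at least 2-fold; under median scaling 701 did, 90.4% of them up against 80.2%. The count was 520 and 543 without TFT 8 h replicates 2 and 3, 288 and 216 without TFT 24 h replicates 1 and 2, and 1777 without the 2 dimmest arrays. With array weights it was 3124, with brightness as a covariate 1892, with detection on all arrays 547, with the replicate block 448, with only the groups compared 369, with LTM 8 h replicate 1 grouped with 24 h 215, and with linear position 87.

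The same comparison for LTM, 24 h against 8 h, showed 16 of 17 histone genes up and 26 of 36 G1/S genes down, with adjusted p = 0.203 and 0.162 with an estimated correlation. RUNDC3B (Entrez ID 154661, GRCh38.p14 chromosome 7, 87628398 to 87832296) rose by 4.41 (SE 0.23, n = 2 and 3 arrays, at least 11.8-fold), RERGL at least 11.4-fold, PLA2G4C by 4.22 (SE 0.17), PSG4, a pregnancy-specific glycoprotein, by 4.03 (SE 0.22) and TCEA3 by 3.83 (SE 0.34). The serpin SERPINA3 fell by 3.58 (SE 0.20), PMEPA1, an inhibitor of TGF-beta signalling, by 3.32 (SE 0.25), COLEC12 at least 6.97-fold, ART3 at least 5.78-fold, and IGFBP3 by 2.86 (SE 0.30). Histone genes had 16 of 17 up, also over the list alone (median 1.62, camera adjusted p = 3.5e-09; 15 up and 1.26 without the 2 dimmest arrays). ATF4 genes had 18 of 33 up and 1 down, 19 and 1 adjusted over the list alone (median 0.65, adjusted p = 9.1e-07), and p53 targets 15 of 28 up and 1 down, also over the list alone (median 0.81, or 0.69 with bounds, adjusted p = 3.2e-05). Noncoding RNAs degraded during translation had 9 of 11 up and 1 down, also over the list alone (median 1.16, adjusted p = 9.6e-04). The lists up had adjusted p = 0.203, 0.130, 0.0629 and 0.430 with an estimated correlation, in that order. G1/S genes had 26 of 36 down, 29 adjusted over the list alone (median -1.09, adjusted p = 4.0e-10), and hypoxia and glycolysis genes 12 of 22 down and 2 up, also over the list alone (median -0.64, adjusted p = 0.0105). Undifferentiated melanoma genes had 9 of 16 down, also over the list alone (median -0.82, adjusted p = 0.01), and cholesterol synthesis genes 7 of 19 down and 2 up, 10 and 2 adjusted over the list alone (median -0.39, adjusted p = 0.0282). The lists down had adjusted p = 0.162, 0.356, 0.430 and 0.203 with an estimated correlation, and the cholesterol call ended without LTM 24 h replicate 2 (0.0891). Mitotic genes had 10 of 38 down and 1 up, 9 and 1 adjusted over the list alone (median -0.33, adjusted p = 0.0339), and ribosomal protein genes 1 of 49 up, none adjusted over the list alone (median 0.19, adjusted p = 0.0327), with adjusted p = 0.550 and 0.696 with an estimated correlation. Both calls ended without LTM 24 h replicate 1, and that of the ribosomal proteins also without LTM 8 h replicate 1 (adjusted p = 0.111) or 3 (0.0511). Without the 2 dimmest arrays the mitotic (0.205), ribosomal protein (0.713) and undifferentiated melanoma calls (0.0508, median -0.48) ended, as they did with brightness as a covariate (0.299, 0.561 and 0.0804). The undifferentiated melanoma list lay 0.45 lower on dim LTM 24 h replicate 1 than on replicate 2. In all 3782 genes changed, 1581 up and 2201 down, 756 and 958 at least 2-fold. Under median scaling, 3614 changed, 25.2% of them up against 41.8%, with the median of all genes at -0.243. LTM 8 h replicate 1, whose labels disagree on its time, was placed at 8 h; grouped with 24 h instead it left no gene past the threshold in limma (1720 at an unadjusted p under 0.05). Linear position left 1913.

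At 8 h the drugs were compared with each other to ask which changes differ between them. FOS was 3.81 higher with LTM than with TFT (SE 0.16, n = 3 and 3 arrays, adjusted p = 3.3e-07), H2AC6 3.52 higher (SE 0.19), TNFAIP3 3.40 (SE 0.21), EGR1 3.21 (SE 0.23) and NUAK2 3.17 (SE 0.16). HAS2 was lower with LTM, at -2.84 (SE 0.28, -1.64 at its other probe), as were WNT5A (-2.41, SE 0.28), KCNS3 (-2.40, SE 0.17), CERK, a ceramide kinase (-2.16, SE 0.15), and CHST1 (at least 4.01-fold). Immediate-early genes were higher with LTM in 23 of 29, also over the list alone (median 1.10, camera adjusted p = 2.7e-14), and NF-kB genes in 14 of 19, 16 with 1 lower adjusted over the list alone (median 1.21, adjusted p = 3.5e-09). Histone genes were higher in 11 of 17, 13 adjusted over the list alone (median 1.12, or 0.83 with bounds, adjusted p = 1.4e-06), and ERK output genes in 9 of 20, 10 adjusted over the list alone (median 0.54, adjusted p = 2.5e-04). These 4 lists had adjusted p = 0.0715, 0.0629, 0.26 and 0.108 with an estimated correlation. Nucleolar genes were higher in 11 of 32, also over the list alone (median 0.38, adjusted p = 0.0026), and noncoding RNAs degraded during translation in 6 of 11, 6 with 1 lower adjusted over the list alone (median 1.06, adjusted p = 0.0299). ATF4 genes were higher in 10 of 33 with 4 lower, 12 and 4 adjusted over the list alone (median 0.19, adjusted p = 0.0202). In that order their results were adjusted p = 0.0715, 0.597 and 0.369 with an estimated correlation. Lower with LTM were G1/S genes in 7 of 36, also over the list alone (median -0.28, adjusted p = 0.0026), and ER chaperone genes in 4 of 22 with 1 higher, 6 and 1 adjusted over the list alone (median -0.42, adjusted p = 0.0147), with HSPA5 at -1.05 (SE 0.13). Heat shock genes were lower in 6 of 17 with 1 higher, 7 and 1 adjusted over the list alone (median -0.38, adjusted p = 0.0147), and oxidative phosphorylation genes in 2 of 32, none adjusted over the list alone (median -0.37, adjusted p = 0.0039). The lower lists had adjusted p = 0.405, 0.131, 0.26 and 0.550 with an estimated correlation. The noncoding RNA call ended without TFT 8 h replicates 2 (adjusted p = 0.0992) or 3 (0.0625) or LTM 8 h replicate 2 (0.0689), and the oxidative phosphorylation call without TFT 8 h replicate 1 (0.0665). With linear position the oxidative phosphorylation median turned to 0.281. On the dim TFT 8 h replicate 1 the noncoding RNA and oxidative phosphorylation lists lay 0.72 and 0.50 above the mean of the other TFT 8 h arrays. The ATF4 call ended with brightness as a covariate (0.0625). In all 2908 genes differed, 1625 higher and 1283 lower with LTM, 608 and 276 at least 2-fold. The count was 1918 without LTM 8 h replicate 1, 842 with that array grouped with 24 h, 7 with linear position and 5324 with array weights.

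At 24 h 17 of 17 histone genes were higher, and 24 of 36 G1/S genes lower, with LTM than with TFT, with adjusted p = 0.196 and 0.229 with an estimated correlation. H4C8 was 5.63 higher with LTM (SE 0.29, n = 2 and 2 arrays, adjusted p = 1.7e-07), NPPB 4.99 (SE 0.33), C6orf58 at least 27.0-fold, IL32 at least 18.3-fold and PGM5P2 at least 19.4-fold higher (2.99 log2 at its other probe). GDF15 was lower with LTM, at -4.72 (SE 0.18), as was ADAM19, a metalloprotease (-4.35, SE 0.27), CEMIP at least 15.6-fold, LRRC17 at least 14.9-fold (-2.73 log2 at its other probe) and HAS2 at least 12.3-fold (-2.12). TYMS was also lower with LTM (-2.41, SE 0.21). Histone genes were higher in 17 of 17, also over the list alone (median 2.83, or 2.64 with bounds, camera adjusted p = 6.3e-10), and nucleolar genes in 16 of 32 with 1 lower, 18 and 1 adjusted over the list alone (median 0.58, adjusted p = 1.9e-04). Noncoding RNAs degraded during translation were higher in 9 of 11 with 1 lower, also over the list alone (median 1.83, or 1.61 with bounds, adjusted p = 1.8e-04), and NF-kB genes in 11 of 19 with 2 lower, 11 and 4 adjusted over the list alone (median 1.05, adjusted p = 0.0026). The higher lists had adjusted p = 0.196, 0.0629, 0.403 and 0.203 with an estimated correlation. Lower with LTM were G1/S genes in 24 of 36, 25 adjusted over the list alone (median -1.07, adjusted p = 1.1e-06), and mitotic genes in 16 of 38 with 1 higher, also over the list alone (median -0.45, adjusted p = 0.0114). Cholesterol synthesis genes were lower in 9 of 19 with 2 higher, also over the list alone (median -0.83, adjusted p = 0.0366), and hypoxia and glycolysis genes in 13 of 22 with 4 higher, also over the list alone (median -0.90, adjusted p = 0.0327). The lower lists had adjusted p = 0.229, 0.465, 0.207 and 0.404 with an estimated correlation. p53 targets did not pass as a list (3 of 28 higher and 10 lower, adjusted p = 0.184). The mitotic call ended without LTM 24 h replicate 1 (adjusted p = 0.0613), that of cholesterol synthesis without replicate 2 of TFT 24 h (0.0543) or LTM 24 h (0.0541), and that of hypoxia and glycolysis under median scaling (0.0501) and without the 2 dimmest arrays (0.0555). The mitotic call also ended without the 2 dimmest arrays (0.062), and with brightness as a covariate the mitotic (0.182), cholesterol (0.0503) and hypoxia calls (0.0706) ended. In all 5185 genes differed, 2262 higher and 2923 lower with LTM, 1341 and 1759 at least 2-fold; under median scaling 29.6% of 4719 were higher, against 43.6%, with the median of all genes at -0.253. Linear position left 1086 genes, and grouping LTM 8 h replicate 1 with 24 h left 3135.

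The last comparison tested whether the change from 8 h to 24 h differed between the drugs. The fitted difference was 4.26 for RUNDC3B (SE 0.32, n = 2 or 3 arrays in each of the 4 groups, adjusted p = 1.7e-05), 4.22 for RERGL (SE 0.27), 3.85 for PSG4 (SE 0.31) and 3.84 for PLA2G4C (SE 0.24), and -4.52 for GDF15 (SE 0.23). The size of these 5 was not measured, because TFT 8 h, and for some TFT 24 h or LTM 8 h, lay below detection. MIX23, which had fallen with TFT, had a difference of at least 3.80 on all 12 arrays (fitted 4.08, SE 0.61, and 3.05 without the 2 dimmest), as TFT 24 h lay below detection. With LTM 24 h below detection, CEMIP had -2.98 or lower (fitted -3.86, SE 0.23) and ART3 -3.19 or lower (fitted -3.79, SE 0.21). For genes detected in all 4 groups, the difference was -4.02 for IL1B (SE 0.28) and -3.52 for TGFBI, an extracellular matrix protein (SE 0.30). Histone genes gained more with LTM in 12 of 17, 14 adjusted over the list alone (median 1.53, camera adjusted p = 9.1e-09; 9 and 0.86 without the 2 dimmest arrays). Noncoding RNAs degraded during translation did so in 5 of 11, 6 adjusted over the list alone (median 1.19, adjusted p = 3.0e-04; 0.0508 without the dimmest arrays). Nucleolar genes gained more in 3 of 32 against 1 that gained less, 1 and none adjusted over the list alone (median 0.23, adjusted p = 0.0206), and ribosomal protein genes in none of 49 (median 0.31, adjusted p = 0.0018). The lists with a positive difference had adjusted p = 0.207, 0.404, 0.131 and 0.572 with an estimated correlation, and the ribosomal protein call ended without LTM 24 h replicate 1 (0.116) or the 2 dimmest arrays (0.678). The difference was negative for p53 targets in 12 of 28, 16 adjusted over the list alone (median -0.73, adjusted p = 3.6e-05), and for immediate-early genes in 13 of 29, 16 adjusted over the list alone (median -0.84, adjusted p = 5.5e-06). It was negative for G1/S genes in 16 of 36, 21 adjusted over the list alone (median -0.82, adjusted p = 1.9e-05), and mitotic genes in 10 of 38, 16 adjusted over the list alone (median -0.73, adjusted p = 1.7e-04). These 4 lists had adjusted p = 0.0629, 0.207, 0.26 and 0.329 with an estimated correlation. It was also negative for ERK output genes in 10 of 20, also over the list alone (median -0.68, adjusted p = 9.3e-04), hypoxia and glycolysis genes in 9 of 22, 10 with 1 positive adjusted over the list alone (median -0.69, adjusted p = 0.0022), and undifferentiated melanoma genes in 5 of 16, 7 adjusted over the list alone (median -0.81, adjusted p = 0.0079; 0.0971 without the dimmest arrays). The last 3 had adjusted p = 0.130, 0.26 and 0.424 with an estimated correlation. With brightness as a covariate the calls of noncoding RNAs (0.14), nucleolar (0.102), ribosomal protein (0.558), mitotic (0.0812) and undifferentiated melanoma genes (0.222) ended. In all 2093 genes differed, 654 positive and 1439 negative, 478 and 1042 by at least 1 log2. Under median scaling 14.2% of 2160 were positive, against 31.2%, with the median of all genes at -0.37. The count was 1222 and 1115 without TFT 24 h replicates 1 and 2, 23 with LTM 8 h replicate 1 grouped with 24 h, and 3258 without the 2 dimmest arrays.

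Genes called in both members of a pair of comparisons were counted by direction. For LTM at 8 h and 24 h, 2173 genes changed the same way (1147 up, 1026 down) and 42 opposite ways. Independence would give 350 up and 316 down. For TFT at both times 13 did (10 up, 3 down; 1.06 and 0.116 under independence) and none moved opposite ways. For TFT and LTM at 8 h 23 did (16 up, 7 down; 3.06 and 1.21 under independence) and 1 moved opposite ways. For TFT and LTM at 24 h 324 did (234 up, 90 down; 121 and 30.1 under independence) and 120 moved opposite ways. Each pair used the same 2 controls, so part of the excess may come from them. In 20 simulations without any drug effect 0 genes were called in both, which leaves out the effects and does not show how far shared controls add to these overlaps. The correlation of the changes across genes, which are not independent replicates, was 0.733 for LTM at both times, 0.313 for TFT at both times, 0.319 for the drugs at 8 h and 0.308 at 24 h. The shared controls alone gave 0.547, 0.547, 0.6 and 0.501 in the simulations. The covariances were 0.481, 0.0377, 0.0529 and 0.147, against 0.0336, 0.0336, 0.0337 and 0.0336 from the controls alone. Without the 2 dimmest arrays the same-direction counts were 3595, 88, 138 and 884, with brightness as a covariate 3411, 89, 164 and 707, with LTM 8 h replicate 1 grouped with 24 h 705, 0, 0 and 59, and with linear position 0 each. For TFT at both times and the drugs at 8 h and 24 h they were 171, 267 and 780 with array weights, 1, 1 and 200 with the replicate block, and 0, 0 and 534 with only the groups compared. For LTM at both times the count was 1126 and 1003 without control replicates 1 and 2. For the drugs at 24 h it was 106 and 107 without control replicates 1 and 2, and 129 and 89 without TFT 24 h replicates 1 and 2. For TFT at both times it was 0 without control replicate 1 and 1 to 6 without any other array but TFT 8 h replicate 1 or an LTM 24 h array. For the drugs at 8 h it was 0 without control replicate 1 and 3 to 14 under the same conditions.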

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

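The tests of array brightness, mislabelled arrays, a 24 h sample among the LTM 8 h arrays and a changed S-phase share were chosen after the results were seen, as were the fits without the 2 dimmest arrays.

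The change between 8 h and 24 h was tested directly within each drug and between the drugs. It passed for 825 genes with TFT and 3782 with LTM, and differed between the drugs for 2093. The difference between the drugs, LTM minus TFT, was 4.26 log2 for RUNDC3B, 4.22 for RERGL, 4.08 for MIX23, 3.85 for PSG4 and 3.84 for PLA2G4C. It was -4.52 for GDF15, -4.02 for IL1B, -3.86 for CEMIP, -3.79 for ART3 and -3.52 for TGFBI. These are fitted values: RUNDC3B, RERGL, PSG4, PLA2G4C and GDF15 lay below detection in TFT 8 h, some also in TFT 24 h or LTM 8 h, so their size was not measured. MIX23 was below detection in TFT 24 h (difference at least 3.80 on all 12 arrays, fitted 3.05 without the 2 dimmest), and CEMIP and ART3 in LTM 24 h (-2.98 and -3.19 or lower). Among the lists whose median difference passed the test, histone genes had 1.53, noncoding RNAs degraded during translation 1.19, ribosomal protein genes 0.315 and nucleolar genes 0.226. The median difference was -0.837 for immediate-early genes, -0.817 for G1/S genes, -0.809 for undifferentiated melanoma genes and -0.734 for p53 targets. It was -0.727 for mitotic genes, -0.689 for hypoxia and glycolysis genes and -0.68 for ERK output genes. None of these 11 lists passed with an estimated correlation (adjusted p = 0.0629 to 0.572). For LTM 8 h against TFT 8 h, with 2908 genes, the 10 splits of the 6 arrays are too few for a share under 0.05. Only 1 split, the real one, gave as many, and the highest of the others gave 0 in limma. A mixed split moves any drug difference into the spread within groups, which lowers its count, so the 0 decides nothing.

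TFT 8 h replicate 1, LTM 24 h replicate 1 and control replicate 2 deviated from their groups along a common axis, their deviations correlating across genes at 0.812, 0.678 and 0.662. A mislabelled array does not account for it: over genes called without it, none of the 3 lay farther than a median of 0.176 of the way to another group. Control replicate 2 could not be placed towards TFT 8 h, with 4 genes called. Lower brightness remains a candidate explanation, since within-group deviations of the second component and of brightness correlated over the 12 arrays (r = -0.86, rho = -0.881, exact permutation p = 0.0347 each, 288 orders within groups), and r was -0.769 without the 2 arrays farthest from the median. Length-dependent RNA or labelling quality may also contribute, as genes with a longer genomic span were lower on each of the 3 arrays (rho -0.425, -0.417 and -0.341 across 10,757 genes, which are not independent). A biological difference between these cultures was not tested, and brightness and RNA quality could not be separated here.

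Histone genes were higher in LTM 24 h than in control, by a median of 2.06. The axis of the dim arrays does not account for it as a whole, since between the brighter arrays, LTM 24 h replicate 2 and control replicate 1, the median was 1.84 with 17 of 17 genes higher, against 2.36 for the other pair. A larger share of S-phase cells would raise replication genes too, if their levels within a cell stayed the same. The G1/S list instead had a median of -1.23, with 28 of its 36 genes called down while 17 of 17 histone genes were called up. Both lists passed in these opposite directions, with adjusted p = 0.194 (G1/S) and 0.207 (histone) with an estimated correlation, so this rests on the genes called singly. Array position remained confounded with the groups. Altered decay, processing or labelling of histone RNA stays open and was not tested. The S-phase share was not measured and levels within a cell may have changed, so the opposite directions do not settle whether that share changed.

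LTM 8 h replicate 1 is labelled 8 h in its title and 24 h in its time field. Over 3017 genes called between the LTM times without it, its median position was 0.008 on a scale from the LTM 8 h mean (0) to the LTM 24 h mean (1), with an upper quartile of 0.124. This argues against a 24 h sample. What the array would look like at a time between the labels was not tested.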

How the results depend on the processing

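The fits without the 2 dimmest arrays, with brightness as a covariate and with crossed pairing were chosen after seeing the data. Followed were 731 values of named genes, of which 717 passed their test, most of them named for that; the brightest members of lists without a call were not followed. Over all settings 16,759 kept direction and side of the threshold, 2059 fell below it, 9 rose past it and 3 changed sign. Over the list tests 2187 kept both, 190 lost the call and 9 changed the direction of the test, though not always the sign of the median. Of the named calls, 524 held in all 12 fits that left out an array. Setting aside these 12 fits, array position and regrouping, 559 held in every other planned setting. A fit with position, or with LTM 8 h replicate 1 at 24 h, estimates a different model. Position follows the groups and cannot be told apart from drug. Detection limits weak genes, with 33.3% to 37.0% of probes detected per array. For the counts below, the cause was not tested.

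In the order TFT 8 h, TFT 24 h, LTM 8 h and LTM 24 h against control, TFT 24 h against 8 h, LTM 24 h against 8 h, LTM against TFT at 8 h and 24 h, and interaction, the counts without an array ranged over 0 to 46, 172 to 856, 1219 to 3304, 4198 to 5933, 216 to 1000, 3017 to 4455, 1918 to 3462, 3851 to 5731 and 1115 to 2491. A group left with 1 array is assumed to vary like the others. Same-direction counts ranged over 0 to 19 (TFT at both times), 1003 to 2650 (LTM at both times), 0 to 34 (drugs at 8 h) and 89 to 440 (drugs at 24 h), and list calls over 81 to 94.

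Linear array position gave 0, 8, 0, 0, 87, 1913, 7 and 1086 genes for the first 8 comparisons and 0 in each overlap. It turned EIF1AX in LTM 8 h (0.44), EIF3J in LTM 24 h (-0.81) and CALR in LTM against TFT at 8 h (0.039). The list test turned for oxidative phosphorylation genes, with medians of 0.358 (TFT 8 h, from 0.081) and 0.52 (TFT 24 h, from 0.016). Others were 0.578 (LTM 8 h), 0.993 (LTM 24 h) and 0.281 (LTM against TFT, 8 h). It turned for histone genes (0.047 at TFT 8 h, 0.553 at TFT 24 h). Ribosomal protein genes had 0.386 (TFT 24 h, from 0.009) and 0.569 (LTM 8 h). Grouping LTM 8 h replicate 1 with 24 h gave 0, 170, 734, 3520, 215, 0, 842, 3135 and 23 genes, and overlaps of 0, 705, 0 and 59. Counts of 0 had 629 (TFT 8 h), 686 (LTM 8 h) and 1375 genes (LTM 24 h) at an unadjusted p under 0.05 in limma with position, and 373 (TFT 8 h) and 1720 (LTM 24 h against 8 h) with the regrouping.

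The replicate block, with replicate numbers that did not pair the arrays (3 of 12 correlated best with their own number), gave 2 (TFT 8 h), 396 (TFT 24 h) and 448 genes (TFT 24 h against 8 h) and overlaps of 1, 1 and 200 (TFT, drugs at 8 h, drugs at 24 h). Only the groups compared gave 0 (676 unadjusted), 1309 and 369 genes for the same comparisons and overlaps of 0, 0 and 534. With crossed pairing, LTM 24 h against control gave 6232 genes, 3347 with the block and 3870 without, all on its own 4 arrays, and TFT 24 h against control on its own 4 gave 2203 with the block and 1309 without. Array weights gave 443, 1706 and 4490 (TFT 8 h, TFT 24 h, LTM 8 h), 3124 (TFT 24 h against 8 h) and 5324 genes (LTM against TFT, 8 h), and overlaps of 171 (TFT), 267 (drugs at 8 h) and 780 (drugs at 24 h). Without the dimmest arrays 208, 1628, 4588, 1777 and, for the interaction, 3258 genes changed, with overlaps of 88 (TFT), 3595 (LTM), 138 (drugs at 8 h) and 884 (drugs at 24 h). The brightness covariate gave 241, 1430, 4290 and 1892 genes (TFT 8 h, TFT 24 h, LTM 8 h, TFT 24 h against 8 h) and overlaps of 89 (TFT), 3411 (LTM), 164 (drugs at 8 h) and 707 (drugs at 24 h).

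Median scaling gave 13 genes for TFT 8 h and overlaps of 7 (TFT) and 10 (drugs at 8 h). No detection filter gave 50 genes for TFT 8 h and an overlap of 37 for the drugs at 8 h. Detection on all 12 arrays gave 384 (TFT 24 h) and 547 genes (TFT 24 h against 8 h) and an overlap of 6 for TFT. A 2-fold threshold, stricter by construction, left 341 (TFT 24 h), 971 (LTM 8 h), 3322 (LTM 24 h), 338 and 1714 genes (24 h against 8 h, TFT and LTM), 884 and 3100 (LTM against TFT, 8 h and 24 h), and overlaps of 4, 743, 14 and 152. With an estimated correlation 2 of the 85 list calls held; fry called 124, 75 of them shared with the 85.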

Other observations

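The tests of CDKN1A against MDM2 and the checks of gene families without the dimmest arrays and under median scaling were chosen after seeing the results. Zinc finger genes, many of them repressors of transcription, rose with LTM: of 270 measured, 123 rose and 5 fell at 8 h (median 0.62, camera adjusted p = 6.9e-13, adjusted p = 0.764 with an estimated correlation), and 140 rose and 21 fell at 24 h (median 0.69, adjusted p = 7.7e-08, adjusted p = 0.884 with an estimated correlation). At 24 h ZNF583 rose by 3.34 (SE 0.21), ZNF79 by 3.33 (SE 0.24) and ZNF283 by 3.11 (SE 0.31). Without the 2 dimmest arrays 163 rose and 11 fell at 8 h and 167 and 24 at 24 h, and under median scaling 90 and 5, and 100 and 22. Of 44 genes named SNORA, for small nucleolar RNAs that guide pseudouridylation of RNA, 15 fell at 8 h of LTM (camera adjusted p = 8.4e-06), 26 at 24 h of LTM (4.0e-04) and 2 at 24 h of TFT (2.7e-05), with none up. Without the 2 dimmest arrays 26, 28 and 9 fell, and under median scaling 14, 29 and 1. In the first order they had adjusted p = 0.764, 0.884 and 0.772 with an estimated correlation. SNORA61 (-2.98, SE 0.40) and SNORA18 (-2.12, SE 0.19) were among those lowest at 24 h of LTM. Of 36 genes named SNORD, for RNAs that guide methylation, 12 fell and 2 rose at 8 h of LTM (adjusted p = 1.9e-04, adjusted p = 0.884 with an estimated correlation). Another test, at 24 h of LTM, did not pass (adjusted p = 0.0805), with 17 down and 3 up, the latter with SNORD139 at 3.87 (SE 0.27) and SNORD95 at 2.83 (SE 0.23). At 24 h of TFT 4 fell and none rose (adjusted p = 7.7e-08, adjusted p = 0.764 with an estimated correlation). These counts also depended on the arrays: without the 2 dimmest, 25 fell and 3 rose at 8 h of LTM, 22 and 3 at 24 h of LTM and 15 fell at 24 h of TFT, and under median scaling 11 and 2, 19 and 3, and 2. Whether the SNORA and SNORD probes read the mature small RNAs or longer transcripts was not tested.

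Of 21 measured collagen genes, 9 fell at 8 h of LTM (5 under median scaling, 10 with 1 up without the 2 dimmest arrays, adjusted p = 0.0333, adjusted p = 0.597 with an estimated correlation). At 24 h 13 fell and 1 rose (15 and 1 under median scaling, adjusted p = 0.0011, adjusted p = 0.52 with an estimated correlation), with COL4A1 at -3.15 (SE 0.21) and COL18A1 at -3.05 (SE 0.17). At 24 h of TFT 7 rose and none fell (5 up under median scaling, adjusted p = 0.0022, adjusted p = 0.52 with an estimated correlation), with COL4A5 at 1.3. Genes named DUSP, many of them phosphatases of MAP kinases, rose in 9 of 19 at 8 h of LTM (7 with 1 down under median scaling, 10 with 2 down without the dimmest arrays), DUSP5 by 2.19 (SE 0.16) and DUSP1 by 2.07 (SE 0.15) (adjusted p = 0.02, adjusted p = 0.727 with an estimated correlation). At 24 h 6 rose and 4 fell, with a median of 0.03 against 0.60, and the test did not pass (adjusted p = 0.592). Families were tested by symbol stem, 75 with at least 15 genes in 300 tests, and 10 passed in the comparisons of LTM with control, 0 of them with an estimated correlation.

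CDKN1A and MDM2, both p53 targets, rose with TFT at 24 h. The change of LTM against TFT at 24 h was -1.48 for CDKN1A (adjusted p = 1.6e-04) and -0.50 for MDM2 (adjusted p = 0.054). These genes differed by -0.979 (SE 0.288). As the pair was picked for this pattern and the value depends on TFT as well as LTM, it does not decide whether CDKN1A rises less with LTM than MDM2 does.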
